A study of Mus musculus with 7 samples.

How the data were processed

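Splenic B cells of 4 wild-type FVB mice and 3 Eµ-miR-155 transgenic mice were isolated with a magnetic B-cell kit and RNA was extracted with Trizol, per the labels' protocols. Biotin-labelled cRNA was hybridised to 1 array per sample, so 7 arrays entered the analysis. The series' design text counts mice, and each sample is taken as 1 mouse. The deposited values are on a log2 scale, as their range shows, and were made by the authors with GCRMA, per the submitters' processing notes, which give no version. GCRMA corrects background from probe sequence, quantile normalizes the arrays and summarises the probes of each probe set. Its correction leaves many probe sets at a common lowest value: 35.6% to 37.0% of the values on each array were at 2.17. Differences of dim genes are therefore compressed or have a lower bound only. Scanner files were not used here. No scan date or slide was used, so no batch could be tested.

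Of 45101 probe sets, 64 are controls, 34945 name 1 gene in the platform annotation, 932 name several and 9160 name none. For 34741 of those with 1 gene the symbol was looked up through its Entrez identifier in a RefSeq table of assembly GRCm38.p6, which changed 0 symbols. The build behind the array is not given in the sources used here, and no coordinates are reported. Probe sets above 4 on at least 3 of the 7 arrays, whatever their group, were tested, which left 20994 (17668 with 1 gene, 551 with several, 2775 with none). A gene was represented by its probe set of highest mean over all 7 arrays, which gave 9517 genes. Of the 439 genes that passed and had another tested probe set, 399 had the same sign in every one, and 0 genes had probe sets passing in both directions. Genes are named only from probe sets that name 1 gene.

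The groups were compared with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with an intensity trend and Benjamini-Hochberg adjustment over all probe sets tested, at an adjusted p under 0.05. The prior degrees of freedom were 1.68. In all, 1949 probe sets passed, 314 of them with no gene and 47 with several. Gene lists were tested with limma's camera, two-sided, with a preset correlation of 0.01 between genes, adjusted over the 27 lists with at least 5 tested genes. Beside each list stands the count of members that passed over all genes and adjusted over the list alone. With a correlation estimated from the data, 0 of the 16 lists that passed with the preset still did, and 2 had an unadjusted p under 0.05, the granulocyte list (camera p = 0.0303) and the natural killer cell list (0.0269); with fry, which asks whether a list's genes move one way on balance and does not compare the list with other genes, 13 lists passed, 12 of the 16 and 1 other. List means were also compared over all 35 splits of the arrays into 4 and 3, an exact test whose smallest p is 0.0286. A gene at or under 4 on every array of one group has a lower bound for its fold, the brighter group's mean against 4, and is given as at least N-fold.

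The groups, the tests, the gene lists, the rule for named genes and most alternative settings were fixed before the data were examined. The rule names the 13 largest increases and 13 largest decreases among genes that passed without overlap of the groups, up to 4 members with the smallest p of each list, and 12 genes known from work on miR-155 and BCL6. The lists cover miR-155 targets, BCL6-repressed genes, corepressors and histone deacetylases, B cell states, cell cycle, signalling and stress pathways, and markers of other cells a spleen isolate may hold. The list of sex-linked genes and that of the miR-155 host gene had 1 tested gene each, Xist (not passing, adjusted p = 0.288) and Mir155hg. A test of genes with miR-155 seed sites in their 3' untranslated regions was planned and was not run, because no transcript sequences were used here.

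The procedure was tested on simulated data with the means and spreads of these arrays. With 100 genes changed by 1 on the log2 scale and 100 by 2, in both directions, 80.0% and 90.0% were called in the right direction, with 5 false calls among 9517 genes. With no change simulated, 0 genes and 0 of 27 lists passed. The simulated genes were independent of each other, so this does not test the list test on correlated genes. Up to 15 lists passed in other splits of the real arrays, all of which keep part of the genotype difference. The alternatives changed the filter, normalization, variance model, array weights, choice of probe sets, threshold and list test, took the replicate number as a block, and left out each array in turn. The block fit also leaves out wild-type replicate 4, which has no transgenic array of its number. Added after the data were seen were the Xist level as a covariate and a fit without both transgenic replicate 3, where T cell genes stood apart, and wild-type replicate 4, where granulocyte genes were above the other wild-type arrays.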

Results

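Gene expression was measured in B cells taken from mouse spleens. The transgenic mice carry miR-155, a small RNA that lowers the messenger RNAs it pairs with, under the Eµ enhancer of the immunoglobulin heavy chain locus, which drives expression in B cells. The controls were wild-type mice of the FVB strain. B cells were separated with a magnetic B-cell isolation kit, and each of the 7 arrays holds RNA from 1 mouse, 4 wild type and 3 transgenic. The values are the authors' GCRMA values on a log2 scale, in which the lowest value in the table is 2.17 and a value at or under 4 is treated here as not above background. Between 46.0% and 47.9% of the probe sets on each array were above 4. The number of arrays limits the precision of every difference.

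The arrays separated by genotype. The first principal component of the tested probe sets held 72.3% of the variance, with the wild-type arrays between -44.8 and -31.4 and the transgenic arrays at 23.9, 38.3 and 85.6. Transgenic replicate 3 lay farthest out. Across probe sets, which are not independent replicates, Pearson's r was 0.987 to 0.993 between wild-type arrays, 0.967 to 0.995 between transgenic arrays and 0.917 to 0.978 between the groups. The labels give no sex. Xist, the RNA that silences an X chromosome in female cells, was at 13.61 to 13.93 on wild-type replicates 1 and 2 and on all 3 transgenic arrays, and at 2.22 and 2.81 on wild-type replicates 3 and 4. The Y-linked gene Eif2s3y was at 9.85 and 11.10 on wild-type replicates 3 and 4 and at 2.17 on the other arrays. By these genes wild-type replicates 3 and 4 were male, and wild-type replicates 1 and 2 and all 3 transgenic arrays were female. The groups are thus not balanced for sex, and genotype is partly confounded with it.

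The comparison of transgenic with wild-type B cells asks which messenger RNAs differ when miR-155 is overexpressed in the B lineage. Genes of other blood lineages had the largest increases in the transgenic isolates, cell cycle genes rose together, and the falls were fewer and smaller. Of 9517 genes tested with limma, 1016 passed an adjusted p under 0.05, 772 higher and 244 lower in the transgenic arrays. Counted by probe set, those with no gene or several included, 1182 were higher and 767 lower. The median change was 0.94 on the log2 scale among the higher genes (0.89 with the 100 genes that were not above background on any wild-type array set at that level) and -0.47 among the lower ones. A change of 2-fold or more was reached by 371 of the higher and 21 of the lower genes. For all 1016 genes the values of the groups did not overlap. Among all genes tested the share without overlap was 29.9%, where chance gives 5.71%. The count fell to 388, 125, 306 and 280 genes when wild-type replicate 1, 2, 3 or 4 was left out, and to 87 without transgenic replicate 2. With the Xist level as a covariate it was 156, and with transgenic replicate 3 and wild-type replicate 4 both left out it was 408; both alternatives were chosen after the data were seen.

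Genes of granule proteins led the increases. Mpo, which encodes myeloperoxidase, stood at 3.98 ± 1.99 (SD, n = 4) in wild type and 13.34 ± 0.55 (SD, n = 3) in transgenic arrays, an increase of 9.36 ± 1.04 (SE, limma adjusted p = 0.00956). Mpo, Prtn3 and Ifi202b were above background on 1 of the 4 wild-type arrays, so their fitted increases are not exact. With values under 4 set at 4 the increase of Mpo was 8.60. Prtn3 and Elane, which encode neutrophil serine proteases, rose by 7.85 (7.63 so set) and 7.54; Elane had the same value of 4.17 on 3 of the 4 wild-type arrays, so its increase is not exact either. Ifi202b, an interferon-inducible gene, rose by 5.60 (4.98 so set). The other 9 of the 13 largest fitted increases were in genes that were not above background on any wild-type array, for which the fold is a lower bound from the transgenic mean against a level of 4. Ctsg, encoding cathepsin G, was at least 105-fold higher, S100a8 and S100a9, which encode the calprotectin subunits, at least 52.0-fold and 15.3-fold, Emb at least 28.1-fold and Car1, the carbonic anhydrase of erythroid cells, at least 26.9-fold. For Gp2, Ear3, Ramp1 and Ms4a3 the bounds were 23.2-fold, 19.9-fold, 16.2-fold and 14.6-fold. All 9 passed the limma test, with adjusted p from 0.000194 for S100a8 to 0.00942 for Car1.

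The 13 largest decreases lay between -1.94 and -1.15. Dmwd had the largest (-1.94 ± 0.44 SE, limma adjusted p = 0.0444), followed by Errfi1, an inhibitor of the EGF receptor, at -1.85 and the kinase gene Tnik at -1.80. Rbpms fell by 1.76. The phosphatase gene Dusp4 changed by -1.51, the p38 kinase gene Mapk12 by -1.48 and Bmf, a BCL2 family member that promotes apoptosis, by -1.35. Ankrd33b, Gm11346, Ms4a4c, 4933426B08Rik and Marchf3 changed by -1.20, -1.19, -1.18, -1.18 (-1.04 with its 1 transgenic value under 4 set at 4) and -1.15. Neo1 was above background on 3 of the 4 wild-type arrays and on no transgenic array, and was at least 1.09-fold lower.

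**Figure D1:**
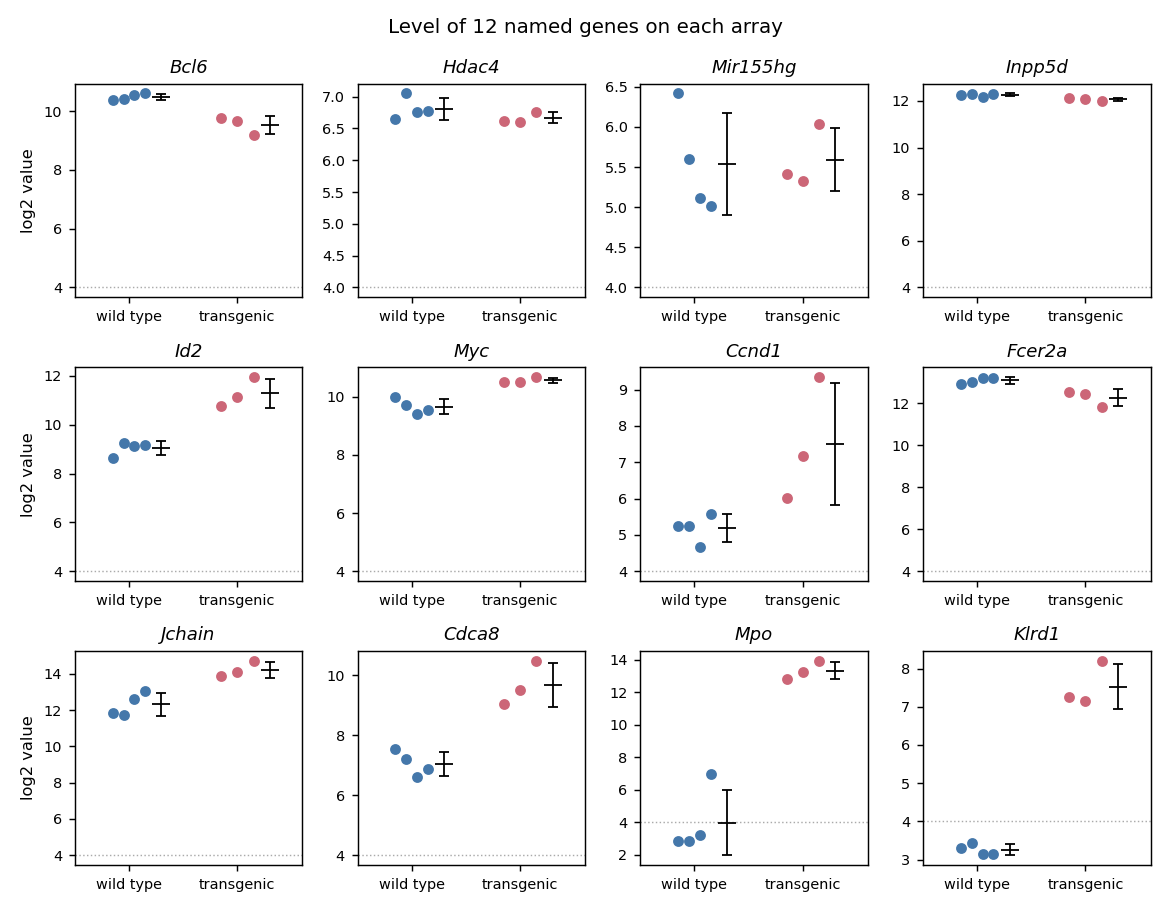
Log2 value (vertical axis) of 12 named genes on each array, with wild type (n = 4) on the left and transgenic (n = 3) on the right of each panel. Points are arrays, the bar beside them is the mean ± SD, and the dotted line marks the background level of 4. Bcl6 lies lower on every transgenic array (10.49 ± 0.11 against 9.54 ± 0.32), while Mir155hg and Hdac4 overlap between the groups.

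The genes tied to miR-155 and to the HDAC4 and BCL6 repressors were measured whatever their values. Bcl6, which encodes a transcriptional repressor of germinal centre B cells, fell from 10.49 ± 0.11 (SD, n = 4) to 9.54 ± 0.32 (SD, n = 3), a change of -0.96 ± 0.15 (SE, limma adjusted p = 0.0205), and its second probe set changed by -1.17. Id2 and Myc, which BCL6 is known to repress, rose by 2.23 ± 0.29 (adjusted p = 0.0144) and 0.90 ± 0.15 (adjusted p = 0.0221). The study of this line is known to have measured these genes, so their directions are not independent evidence. On the same arrays the tested natural killer cell, dendritic cell and cell cycle genes were higher by medians of 3.99, 1.99 and 2.41. Which cells of the isolates carry the rises of Id2 and Myc was not tested. Hdac4, a described miR-155 target, did not pass (-0.14 ± 0.11, adjusted p = 0.402). Nor did Inpp5d, which encodes the phosphatase SHIP1 (-0.20 ± 0.06, adjusted p = 0.0684), Cebpb (0.49, adjusted p = 0.0749) or Spi1 (-0.14, adjusted p = 0.551). Mir155hg, the host transcript of miR-155, was at 5.54 ± 0.64 in wild type and 5.59 ± 0.39 in transgenic arrays (adjusted p = 0.937). The labels do not say whether its probe set lies within the transgene, so it does not check the labels. Ccnd1 (cyclin D1) did not pass with its brightest probe set (2.32 ± 0.73, adjusted p = 0.0959) or with a dimmer one (1.38, adjusted p = 0.135). Another, not above background on any wild-type array, passed (adjusted p = 0.0372). Il6 was at the lowest value on every array, and Socs1 and Ccl3 were above background on transgenic replicate 3 alone, at 7.44 and 6.95. The calls of Bcl6 and Id2 were lost without wild-type replicate 2 (adjusted p = 0.0647 and 0.0542) or transgenic replicate 2 (0.0745 and 0.0696), that of Bcl6 also without wild-type replicate 3 or 4 (0.0577 and 0.0578), and that of Myc without wild-type replicate 2 or 4 or transgenic replicate 2 (0.0678, 0.0601 and 0.0820) or without both transgenic replicate 3 and wild-type replicate 4 (0.100). With no filter, with the Xist covariate or with the replicate number as a block, which leaves out wild-type replicate 4, none of the 3 passed. The changes themselves ran from -1.08 to -0.74 for Bcl6, from 1.90 to 2.49 for Id2 and from 0.70 to 1.01 for Myc over all alternatives. Over all alternatives the adjusted p of Bcl6 ran from 0.00164 to 0.171, that of Id2 from 0.00109 to 0.127 and that of Myc from 0.00333 to 0.171, with the sign kept.

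Described miR-155 targets had a small negative median change, and the call of a shift depended on the test. Of 33 targets tested, 2 were higher, 1 was lower and 30 did not pass (4 higher and 12 lower when adjusted over the list alone). Hivep2 fell (-0.57, adjusted p = 0.0339). Myb, a regulator of blood progenitors, rose by 3.75 and Ikbke by 0.60; Zfp652 did not pass (-0.69, adjusted p = 0.0512). The list's median change was -0.14 and its mean 0.10, so they differ in sign, and camera gave the downward direction (adjusted p = 0.0062). That call was lost with an adjusted p = 0.376 with an estimated correlation. The median lay at the 0.17th percentile of 10000 random lists matched on mean level, a comparison chosen after the median was seen. These lists were drawn gene by gene, which treats genes as independent and does not measure the variation between mice. The exact permutation p of the list's mean over the 35 splits of the arrays was 0.229, two-sided. On the same arrays the mature B cell list was lower by a median of -0.26.

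BCL6-repressed genes moved both ways. Among 18 tested, 3 rose, 2 fell and 13 did not pass (5 and 3 when adjusted over the list alone, which is not independent evidence for the genes the study measured). Bcl2l1, encoding the survival protein BCL-XL, rose by 0.64 beside Id2 and Myc, while Gpr183, a chemotactic receptor, and Cdkn1b, encoding the cyclin-dependent kinase inhibitor p27, changed by -0.84 and -0.43. By camera the list did not shift as a whole (median 0.05, adjusted p = 0.915). Its mean change was 0.33, and its mean was 9.55, 9.61 and 10.07 on the transgenic arrays against 9.29 to 9.47 in wild type. The exact permutation p of that mean was 0.0286, the smallest possible. Of the 18 genes, 9 had a positive change. The mean holds Id2 (2.23), Ccnd1 (2.32, not passing) and Myc (0.90), genes the study of this line is known to have measured. This p is therefore not independent evidence of a shift of the list. Of 17 corepressors and histone deacetylases, Bcl6 itself was the 1 that passed, over all genes and when adjusted over the list alone, while Bcor (-0.27, adjusted p = 0.058) and Hdac10 (-0.62, adjusted p = 0.0922) did not, and neither did the list (adjusted p = 0.0753; 0.0440 without wild-type replicate 2, and 0.0440 to 0.376 over its alternatives).

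Few genes of mature B cell identity passed as lower, and some plasma cell and germinal centre genes passed as higher. Of 21 mature B cell genes, 2 passed as lower, 0 as higher and 19 did not pass (3 lower when adjusted over the list alone). Only 2 of the 21 had a positive change. Fcer2a, encoding the IgE receptor CD23, fell (-0.82, adjusted p = 0.0451), as did the B cell receptor inhibitor gene Cd72 (-0.30, adjusted p = 0.0313), while Cd55 (-1.28, adjusted p = 0.0587) and Cd22 (-0.27, adjusted p = 0.0744) did not pass. The list shifted down by a median of -0.26 (camera adjusted p = 1.16e-04; adjusted p = 0.376 with an estimated correlation). Plasma cell genes shifted up by a median of 0.63 (adjusted p = 2.49e-04; adjusted p = 0.376 with an estimated correlation), with 3 of 18 higher (13 higher and 1 lower when adjusted over the list alone). The antibody joining chain gene Jchain rose by 1.91 ± 0.38 (SE), Pdia4 by 0.68 and the elongation factor gene Ell2 by 0.61. Germinal centre genes also shifted up (median 1.05, adjusted p = 0.00542; adjusted p = 0.376 with an estimated correlation), with 4 of 15 higher and 1, Bcl6, lower (7 and 1 when adjusted over the list alone). Basp1, Gcsam and Eaf2 rose by 3.16, 2.53 and 1.99. Gcsam was above background on 1 wild-type array, and with values under 4 set at 4 its increase was 1.79. All 3 genes were lower on wild-type replicates 3 and 4 than on 1 and 2, the division that sex-linked genes show. Their fitted rises are therefore larger than against replicates 1 and 2 alone. The germinal centre list mean was 7.17 and 6.88 on wild-type replicates 1 and 2 and 6.32 and 6.59 on 3 and 4. Without transgenic replicate 3 the mature B cell median was -0.16 and the plasma cell median 0.40, and both lists still passed. On the same arrays the tested granulocyte genes were higher by a median of 5.70 and the tested erythroid genes by 2.73.

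Some precursor B cell and marginal zone genes rose, and the shifts of these lists did not pass over the tested genes. Of 13 precursor B cell genes 4 were higher and 0 lower (7 and 0 when adjusted over the list alone): Flt3 (1.86), Kit (3.99; above background on 2 wild-type arrays, 3.93 with values under 4 set at 4), Cd93 (2.43) and Myb, which blood progenitors also express. The list's adjusted p was 0.064. It was 0.0474, 0.0484 and 0.0483 without wild-type replicate 2, 3 or 4 and 0.0169 without transgenic replicate 3. With no filter it was 0.0333, with quantile normalization 0.0363 and with the Xist covariate 0.0151, and over its alternatives it ran from 0.0120 to 0.376. Of 15 marginal zone and B1 genes 4 were higher and 0 lower (8 and 1 when adjusted over the list alone; list adjusted p = 0.0819), among them Asb2 (1.36), the integrin gene Itgb1 (1.14) and Plac8 (0.31), while Pstpip2 was at least 3.54-fold higher. This list passed with no filter (adjusted p = 0.00486) and without transgenic replicate 3 (0.00719), and over its alternatives its adjusted p ran from 0.00486 to 0.384. B cell activation genes did not shift as a list (adjusted p = 0.915). Of 18, Myc and the cytokine subunit gene Ebi3 (0.70) rose and Cd40, encoding a receptor for T cell help, fell (-0.44), with 4 higher and 2 lower when adjusted over the list alone. The tested blood progenitor genes were higher on these arrays by a median of 2.66.

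Cell cycle genes rose together. Of 33 tested, 26 were higher and 0 lower (32 and 0 when adjusted over the list alone), and the median change was 2.41 (camera adjusted p = 1.20e-14; adjusted p = 0.376 with an estimated correlation). The mitotic kinase genes Plk1 and Bub1 rose by 2.53 ± 0.36 and 3.84 ± 0.51 (SE; Bub1 was above background on 1 wild-type array, and 3.47 higher with values under 4 set at 4), and the chromosomal passenger gene Cdca8 rose by 2.63 ± 0.37 (SE). Ccne2, encoding cyclin E2, was at least 1.64-fold higher. The list mean was 6.34 to 7.21 on the wild-type arrays and 8.22, 8.55 and 9.63 on transgenic replicates 1, 2 and 3. The granulocyte list was also higher on each transgenic array than on any wild-type array.

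Some genes of protein folding in the endoplasmic reticulum and of glycolysis rose, and most did not pass. Of 20 unfolded protein response genes 6 were higher and 0 lower (15 and 0 when adjusted over the list alone), including Sdf2l1 (1.29), Pdia4 and Manf (0.59); the list's median was 0.36 (adjusted p = 1.80e-05; adjusted p = 0.376 with an estimated correlation). Glycolysis had 6 of 15 genes higher and 1 lower (9 and 1 when adjusted over the list alone; median 0.45, adjusted p = 0.00542; adjusted p = 0.392 with an estimated correlation), with rises of Hk2 (1.14), Tpi1 (0.80) and Pgam1 (0.77). The tested granulocyte genes were higher by a median of 5.70 on the same arrays.

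The mean of interferon-stimulated genes was highest on transgenic replicate 3. Of 27 genes 2 passed as higher and 1 as lower, the same counts as when adjusted over the list alone. Mx1, an antiviral GTPase gene, and Oas1a rose by 2.20 and 1.88, Stat2 fell (-0.40), and Usp18 did not pass (adjusted p = 0.0843). The list's median was 0.61 (adjusted p = 0.00611; adjusted p = 0.563 with an estimated correlation). Its mean was 8.37 and 8.12 on transgenic replicates 1 and 2, 9.53 on replicate 3 and 7.29 to 8.13 in wild type. Without transgenic replicate 3 the list's adjusted p was 0.262 with a median of 0.25, with the Xist level as a covariate it was 0.188, and over its alternatives it ran from 9.68e-05 to 0.563. T cell genes were also high on replicate 3.

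Other signalling groups changed in few members. Of 25 PI3K and AKT genes, Pik3r2 rose (0.45) and Foxo1, encoding a transcription factor that AKT inhibits, fell (-0.55); 2 were higher and 1 lower when adjusted over the list alone, and the list did not shift (adjusted p = 0.107). Of 19 apoptosis genes Bcl2l1 rose and Bmf fell, with the same counts when adjusted over the list alone (list adjusted p = 0.651). Of 17 NF-kB and cytokine genes 1 rose and 3 fell (2 and 3 when adjusted over the list alone; list adjusted p = 0.0893, median -0.09 and mean 0.10, which differ in sign). The chemokine gene Ccl5, also a natural killer cell gene, rose by 3.59, and Rel (-0.87), Birc3 (-0.36) and Ltb (-0.25) fell. The list passed without wild-type replicate 1 (adjusted p = 0.0360) or transgenic replicate 3 (0.00474), with a range of 0.00148 to 0.392 over its alternatives. MHC class II genes had 1 of 13 lower, Cd40, and 0 when adjusted over the list alone (list adjusted p = 0.0753); H2-Ob did not pass (-0.32, adjusted p = 0.0762). That list passed without wild-type replicate 3 or 4 (adjusted p = 0.0454 and 0.0406) and with the Xist covariate (0.0131), with a range of 0.0131 to 0.392. Of 15 p53 response genes Zmat3 rose (0.48), 0 passed when adjusted over the list alone, and the list did not shift (adjusted p = 0.773). Immediate early and heat shock genes, which handling of cells can raise, shifted down by a median of -0.21, which was -0.36 without wild-type replicate 1, -0.059 without wild-type replicate 3 and -0.12 without transgenic replicate 3 (adjusted p = 0.0402; adjusted p = 0.46 with an estimated correlation). None of 17 passed alone, Zfp36 (-0.63) and Klf6 (-0.36) included, and 2 were lower when adjusted over the list alone. The shift did not pass without wild-type replicate 2 or 3 (adjusted p = 0.0542 and 0.261) or transgenic replicate 1 or 2 (0.0649 and 0.0642), with no filter (0.0645), with the mean of a gene's probe sets (0.0833), with the replicate number as a block (0.0546) or with fry (0.307). With the Xist level as a covariate the median was 0.0064 (adjusted p = 0.384), so no shift was left. Over its alternatives the adjusted p ran from 0.00132 to 0.460.

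**Figure D2:**
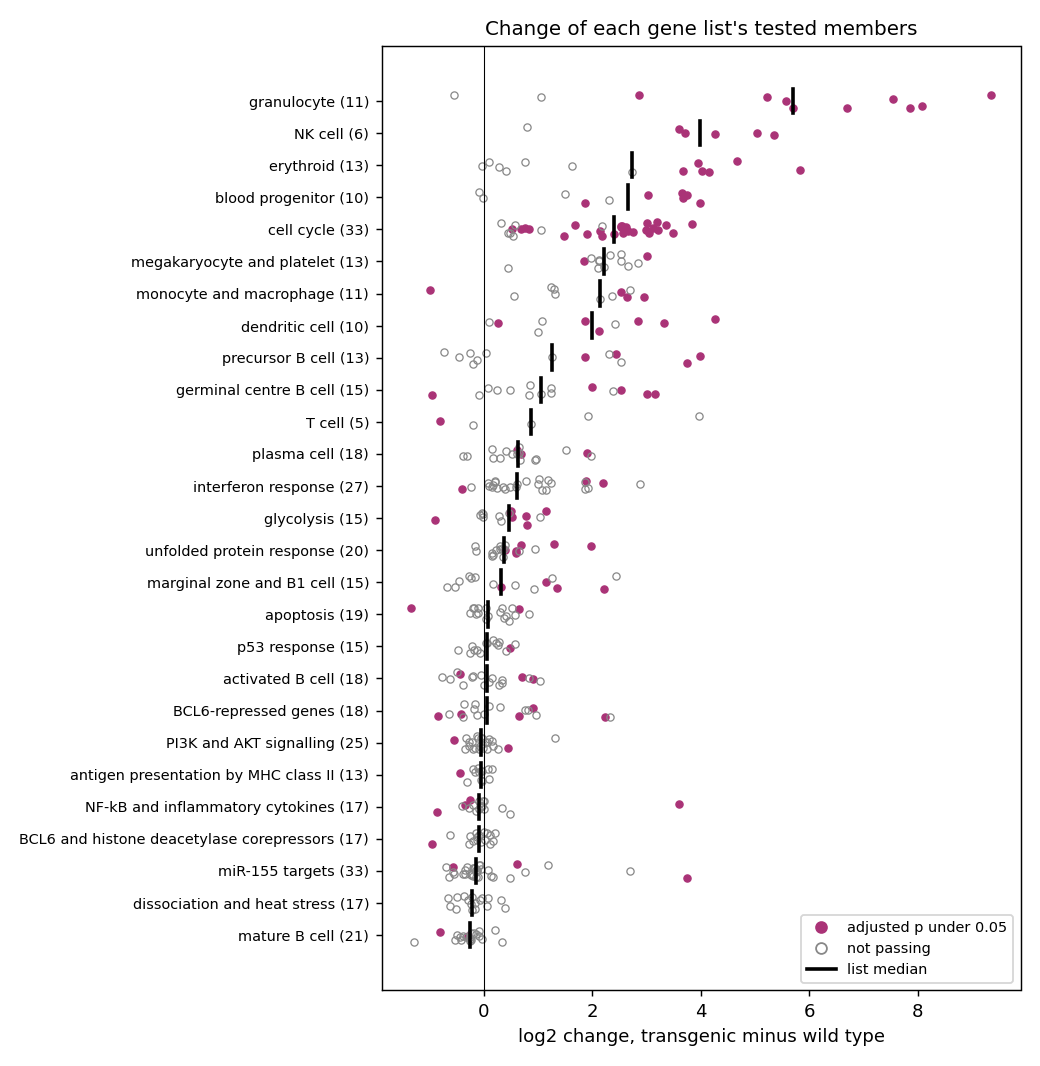
Log2 change, transgenic minus wild type (horizontal axis), of every tested member of each gene list with at least 5 tested genes. Filled points passed an adjusted p under 0.05, open points did not, the black bar is the list's median and the number of genes is in brackets. Among the genes that passed the filter the granulocyte list has the largest median (5.70) and the mature B cell list the lowest (-0.26); over all list genes with no filter the granulocyte median is 2.05, below those of the cell cycle (2.17) and megakaryocyte and platelet lists (2.12).

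Markers of other blood cells were higher in the transgenic isolates. The filter keeps genes that are above 4 on 3 arrays, which the transgenic arrays alone can meet, so the medians of dim lists are given over the tested genes and over all list genes with no filter. Of 11 granulocyte genes tested 9 were higher and 0 lower (10 and 1 when adjusted over the list alone), with a median of 5.70, or 3.94 with the 5 genes that were not above background in wild type set at that level (camera adjusted p = 6.04e-10; adjusted p = 0.376 with an estimated correlation). Over all 21 granulocyte genes the median was 2.05, and 3 of them were above background on all wild-type arrays. Chil3, a myeloid chitinase-like gene, was at least 11.9-fold higher. Of 6 natural killer cell genes tested 5 rose (6 when adjusted over the list alone; median 3.99, 3.39 at the bound and 1.31 over all 15, adjusted p = 4.92e-06; adjusted p = 0.376 with an estimated correlation), with Klrd1, Nkg7 and Klrk1 at least 11.5-fold, 9.48-fold and 3.78-fold higher. Of 13 erythroid genes tested 6 rose (9 when adjusted over the list alone; median 2.73, 2.29 at the bound and 1.03 over all 24, adjusted p = 5.99e-06; adjusted p = 0.376 with an estimated correlation). Aqp1, encoding a water channel, Tal1, a transcription factor gene, and Slc4a1, encoding the band 3 anion exchanger, were at least 19.5-fold, 5.93-fold and 4.96-fold higher. Without transgenic replicate 3 the median of the tested erythroid genes was 1.49, and the list still passed.

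Megakaryocyte and platelet genes were present in wild type, 12 of 17 on all its arrays, and shifted up by a median of 2.21 (adjusted p = 1.39e-05; adjusted p = 0.384 with an estimated correlation). Of 13 tested, 2 passed (12 when adjusted over the list alone), the chemokine gene Pf4 (3.01) and Gp9 (1.85), while Vwf did not (2.33, adjusted p = 0.0505). Of 10 dendritic cell genes 6 rose (8 when adjusted over the list alone), among them Fscn1 (2.12) and Xcr1, at least 2.96-fold. The members with the smallest p, Klrd1 and Flt3, rose too. Klrd1 is also in the natural killer cell list, and Flt3 in the precursor B cell and blood progenitor lists. Of the 15 dendritic cell genes on the array, 3 are in another list, so this rise is not fully separate from theirs. The median was 1.99, 1.71 at the bound and 1.73 over all 15 (camera adjusted p = 3.72e-06 over the tested genes, and 0.376 with an estimated correlation). Monocyte and macrophage genes had 3 of 11 higher and 1 lower (8 and 1 when adjusted over the list alone; median 2.14, 1.31 at the bound, 1.25 over all 24 and 1.36 with the mean of a gene's probe sets, adjusted p = 0.00389; adjusted p = 0.392 with an estimated correlation). Fcgr3 and the lysosomal gene Cd68 rose by 2.95 (2.84 with values under 4 set at 4, since 1 wild-type array was above it) and 2.63, Ccr2 was at least 2.11-fold higher, and Spic fell (-0.99). Blood progenitor genes had 6 of 10 higher and 0 lower (8 and 0 when adjusted over the list alone; median 2.66, 2.08 at the bound and 0.67 over all 20, adjusted p = 1.79e-04; adjusted p = 0.376 with an estimated correlation). Of the 3 stromal genes tested none passed, and 1 was higher and 1 lower when adjusted over the list alone.

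T cell genes were high on transgenic replicate 3. Of 5 tested, 0 passed as higher and 1, Cd2, as lower (-0.81), with 2 and 1 when adjusted over the list alone, and the list did not pass over these (adjusted p = 0.697). Over all 21 T cell genes on the array, with no filter, it passed as higher (median 1.32, adjusted p = 0.0148); their mean was 7.41 on replicate 3, 3.39 and 3.49 on the other transgenic arrays and 3.30 to 3.40 in wild type. Without replicate 3 the 5 tested genes had a median of 0.34 (adjusted p = 0.991), and over its alternatives its adjusted p ran from 0.0148 to 0.991. Cd3g, part of the T cell receptor complex, was at 9.86 on replicate 3, 4.02 and 4.55 on the other transgenic arrays and 2.17 in wild type, and Lat was at 11.41 there against 5.82 to 6.76 on the other 6 arrays. Neither passed (adjusted p = 0.112 and 0.303). Cd2 was at 11.52 to 11.86 in wild type, where Cd3g was at 2.17, and was lowest on transgenic replicate 3 (10.46). Its fall therefore does not follow Cd3g and Lat and does not report fewer T cells.

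**Figure D3:**
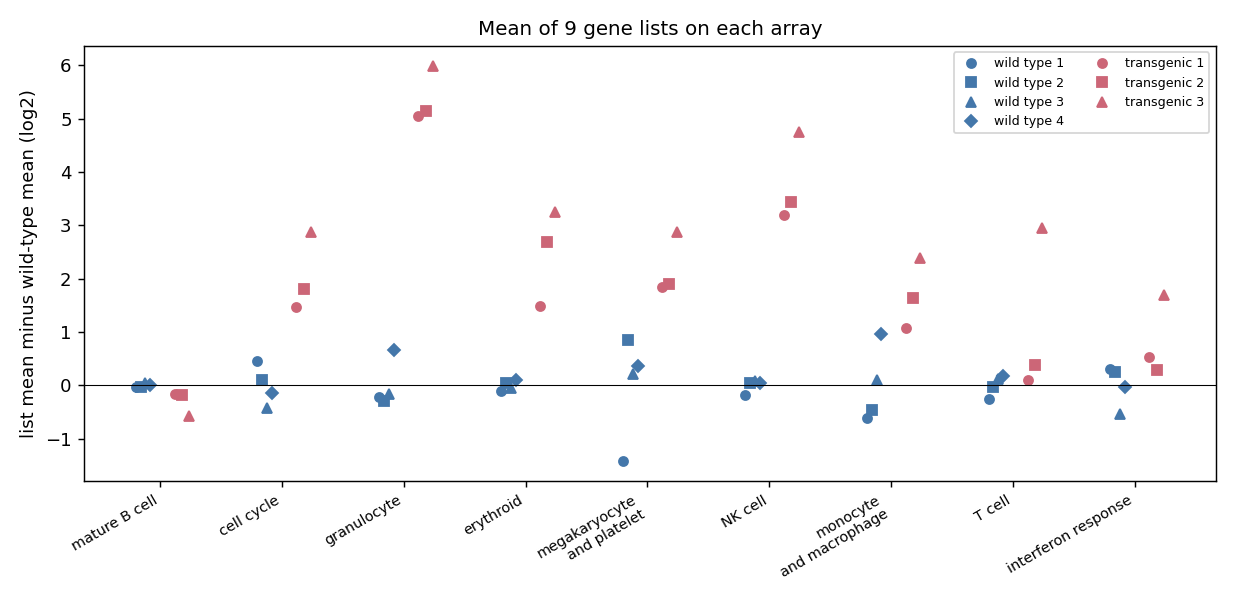
Mean log2 value of the tested genes of 9 lists on each array, minus the list's wild-type mean (vertical axis). Blue points are the 4 wild-type arrays and red points the 3 transgenic arrays, with 1 marker shape per replicate number. The granulocyte mean is 9.05, 9.14 and 9.99 on the transgenic arrays against 3.71 to 4.66 in wild type, and the T cell mean is set apart on transgenic replicate 3 (9.34 against 6.48 and 6.77).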

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

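The test of mature neutrophil genes and the counts over other splits of the arrays were set before their results were seen; all other tests in this part were chosen afterwards. Of 84 named genes with a wild-type value above background, 9 had 1 wild-type array far from the other 3, and 3 of 28 list means did. Chance gives about 1 such set in 20, a rate that does not hold for Mpo, Prtn3 and Fcgr3, whose other 3 arrays were not above background, or for Elane, whose other 3 values were the same. The measure is the gap to the nearest array as a share of the whole range.

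Wild-type replicate 4 stood above the other wild-type arrays in myeloid genes. Mpo was at 6.95 there against 2.85 to 3.23 (gap 0.907 of the range), Prtn3 at 5.30 against 3.68 to 3.75 (0.957), Elane at 5.46 against 4.17 (1) and Fcgr3 at 4.56 against 3.85 (1). The granulocyte list mean was 4.66 against 3.71 to 3.83 (0.871). On wild-type replicate 1, Lat was at 5.82 against 6.50 to 6.60 (0.875), Gp9 at 6.18 against 7.36 to 7.38 (0.982), the natural killer list mean at 3.74 against 3.94 to 3.98 (0.834) and the stromal list mean at 8.86 against 9.09 to 9.14 (0.832). Wild-type replicate 3 had Hivep2 at 9.51 against 9.86 to 9.88 (0.953) and Pdia4 at 10.13 against 10.21 to 10.22 (0.876). Sdf2l1 was at 8.75 on wild-type replicate 2 against 8.17 to 8.24 (0.876).

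Genes were also sought that lay above 6 on 1 array and at or under 4 on the other 6. There were 73 on transgenic replicate 3, 1 (Camp, at 6.67) on transgenic replicate 1 and 0 on each wild-type array. Those on replicate 3 included Thy1 (10.78), Cd3d (10.70), the T cell receptor segments Trav9d-3 (10.69) and Trgv1 (9.68), Dntt (10.64), an enzyme of receptor gene rearrangement, and Ccr9 (10.44), all at or under 2.69 elsewhere; these names were chosen after their values were seen. Of the 21 T cell genes on the array, 18 (85.7%) were over 1 log2 unit above both other transgenic arrays there, which is what T cells or T-lineage precursors in that isolate may give. This count restates the pattern that prompted it, so it is not separate support for such cells. Of these 21 genes, 4 were above background on all wild-type arrays, and 2 are in another list. The mean of the 21 genes was 3.39 and 3.49 on the other transgenic arrays and 3.30 to 3.40 in wild type. Transgenic replicate 3 also had the lowest mature B cell mean, 12.70 against 13.09 and 13.11. A disease state of that mouse stays open as untested.

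Myeloid, erythroid and natural killer genes were higher on all 3 transgenic arrays. Array scaling, which moves genes of one level alike, is argued against for the 14 granulocyte, erythroid and natural killer genes with a wild-type mean above 4, whose median change was 0.92, while 2.5% of 10000 random lists matched on wild-type mean had a median over 0.25, the highest 0.78. So is RNA quality, since the 3' minus 5' difference of Gapdh differed between the groups by -0.034 (SD 0.0697 among wild-type arrays). Mature neutrophils as the source on all 3 arrays are argued against by their late genes (Ltf, Camp, Ngp and 4 others), with a median transgenic mean of 3.29. A smaller share of them stays open on replicate 1, with Ngp, Camp and Ltf at 7.68, 6.67 and 5.15, and on replicate 3, with Ngp at 5.80. These late genes leave out S100a8 and S100a9, granulocyte genes with transgenic means of 9.70 and 7.94. A lower share of B cells that raises every other cell type alike stays open, because its test cannot decide. Over all list genes with no filter, the granulocyte list rose more than the megakaryocyte and platelet list. The excess was 1.92, 1.36 and 0.71 on transgenic replicates 1, 2 and 3, where 2 SD of that difference among wild-type arrays is 1.49. On all wild-type arrays 3 of 21 granulocyte genes were above background, against 12 of 17 megakaryocyte and platelet genes. Values at the lowest level can therefore compress the granulocyte rise. Cells of other lineages, with granule genes of myeloid precursors such as Mpo (transgenic mean 13.34) and globin (the probe set shared by the adult beta-globin genes at 12.39 against 5.48), may be present despite the B-cell kit, since the mature B cell list was lower on every transgenic array (exact permutation p = 0.0286, the smallest possible, two-sided), and whether the genotype changes which cells the spleen or the isolate holds, or what B cells express, stays open as untested.

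Bcl6 was lower on all 3 transgenic arrays. Fewer B cells would lower it by about as much as other B cell genes, but its change was below the median of the 21 mature B cell genes by -0.69. That is beyond 2 standard errors of its own change (0.30), in which the error of the median and the spread of the 21 genes were not counted. Of the 21, 1 fell further. The mature B cell genes are bright, which could compress their change: the 3 with a mean under 12 had a median of -0.42. A change in which B cell subsets the isolates hold stays open, as does the genotype.

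Chance assignment of the arrays was tested by refitting all 35 splits into 3 and 4. The real split called 1016 genes and the others at most 0, so 1 of 35 gave as many, the smallest share that 35 splits can give. Splits that mix the groups put the genotype difference into the spread within groups, which lowers their counts. The test does not tell the genotype from other differences between the groups, such as that in sex. For lists past the threshold, 1 of 35 splits reached the real count of 16, and the highest of the others was 15. Splits that mix the groups or part the wild-type arrays thus also passed many lists with the preset correlation. None of these splits is free of the genotype difference, since 3 transgenic arrays cannot be shared equally between 3 and 4. Their counts therefore do not show how many lists pass with no difference.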

How the results depend on the processing

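The fits with the Xist level as a covariate and without both transgenic replicate 3 and wild-type replicate 4 were chosen after the data were seen. The main count of 1016 genes (772 higher, 244 lower) became 116 (100 and 16) with no filter, 2763 (1835 and 928) with array weights, which gave transgenic replicate 3 a weight of 0.195, 392 (371 and 21) at 2-fold or more, 92 (83 and 9) at an adjusted p under 0.01, 156 (137 and 19) with the Xist covariate and 408 (343 and 65) without both arrays. Leaving out 1 array gave 87 to 1074 genes (80 to 803 higher, 7 to 271 lower). The other settings gave 896 to 1200. Apart from the thresholds and the loss of samples, the cause was not tested. Genes of the main count kept their sign wherever tested, except 1 without the _x_at and _s_at probe sets and 4 with the mean of a gene's probe sets. Of 87 named genes that passed, 19 to 75 kept their call with 1 array left out, 28 with the Xist covariate and 47 without both arrays. The first component held 68.4% to 75.9% of the variance with 1 array left out. Same-numbered arrays correlated in their deviations from the group means by -0.04, -0.14 and -0.29. No transgenic array correlated best with its own number. Deviations within a group depend on each other, and transgenic replicate 3 lies apart, so these values cannot exclude a pairing. With the replicate number as a block, which also leaves out wild-type replicate 4, 3 genes passed (3 higher, 0 lower, and 1956 at an unadjusted limma p under 0.05). Without that array and with no block, 280 genes passed.

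The 16 lists past the threshold became 0 with an estimated correlation (miR-155 targets: median -0.14, adjusted p = 0.376) and 13 with fry (12 of the 16; not the mature B cell, interferon, monocyte and stress lists). In the other settings 15 to 19 lists passed, 14 to 16 of them from the 16. Lists not past the threshold turned in direction: BCL6-repressed genes (0.05; -0.10 to 0.21 with 1 array left out, 0.050 with the Xist covariate, where camera's direction but not the median turned, -0.067 without both arrays), B cell activation genes (-0.11 to 0.14 with 1 array left out, -0.10 without both) and T cell genes (0.39 without both, by camera's direction; they passed with no filter, adjusted p = 0.0148). Mir155hg, at 0.05, was -0.17 to 0.35 with 1 array left out, -0.080 after quantile normalization, -0.13 with array weights, -0.12 with the block, -0.43 with the Xist covariate and -0.34 without both arrays; it passed in none. The test of miR-155 seed sites was not run. Signal over background limits the folds of dim genes.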

Other observations

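Of 15 globin probe sets, the 4 that name several genes, and so entered no gene count, rose in the transgenic isolates, and none of the 11 that name 1 gene passed, 10 of which were too dim to be tested. The probe set shared by the adult beta-globin genes rose from 5.48 ± 1.20 (SD, n = 4) to 12.39 ± 0.95 (SD, n = 3), a change of 6.90 ± 0.73 (SE, limma adjusted p = 0.00815). The 2 brighter of the 3 probe sets shared by Hba-a1 and Hba-a2, the adult alpha-globin genes, rose by 5.28 and 5.01 (adjusted p = 0.0238 and 0.0312). Probe sets for the embryonic genes Hbb-y, Hbb-bh1 and Hba-x were not above background on any array, and one that names Hba-a2 alone did not pass (-0.34, adjusted p = 0.0980). These probe sets were chosen after the data were seen.

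Sex-linked genes divided the wild-type arrays. Kdm5d and Uty were at 7.99 and 7.05 on wild-type replicate 3 and at 8.50 and 8.37 on replicate 4, and at the lowest value elsewhere, while Tsix was at the lowest value on every array. Of the markers of other lineages, 7 of 24 monocyte and macrophage genes, 7 of 24 erythroid genes, 3 of 21 granulocyte genes and 2 of 15 natural killer genes were also above background on all 4 wild-type arrays.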
